A study of Rattus norvegicus with 6 samples.

How the data were processed

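Mammary tumors of female Sprague-Dawley rats were profiled by RNA sequencing. Per the labels' protocols, the rats received N-methyl-N-nitrosourea (MNU), a direct-acting alkylating carcinogen that induces mammary tumors in rats, at 50 mg/kg by intraperitoneal injection at 21 days of age. From 1 week later they were given corn oil by oral gavage (the vehicle, 100 µL) or 50 mg/kg diallyl trisulfide (DATS), an organosulfur compound of garlic, in corn oil, 5 times a week for 10 weeks. The 6 libraries fell into 2 groups of 3, vehicle and DATS, taken from the treatment label of each sample. Total RNA was extracted with a column kit and libraries were made by standard Illumina procedures, per the labels' protocols. The labels do not say whether the 3 tumors of a group came from separate rats, so the p-values of single genes measure the spread between these tumors and no more.

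The table deposited by the authors gives 1 FPKM value (fragments per kilobase of gene, scaled for sequencing depth) per gene and tumor, with rat Ensembl gene identifiers and symbols, per the file headers. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here, and for that reason no coordinates are printed. The table had 32545 genes, of which 20891 were above 0 in at least 1 tumor. A total of 503 symbols occurred on more than 1 row, those of many small RNAs among them, and rows with the same symbol were kept apart. Reads of genes with near-identical copies, ribosomal protein genes among them, may have been divided between rows by the counting, and the values of single such genes are uncertain. Which other genes this touches was not examined, Ndufa1 and Tma7 included. Strand handling is likewise not given in the sources used here, so reads of overlapping antisense genes could not be separated.

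The depth was recovered from the deposited FPKM values. Within a tumor, the values of a gene are whole multiples of the value of 1 read, and comparing genes of low value between tumors gave the relative value of 1 read. Whole reads, within a tolerance of 1e-06, were obtained for 100.0% of the 20891 genes above 0. The implied gene lengths were then scaled so that they were whole numbers of bp, and for 764 genes whose implied length was not whole a common divisor of the reads was put back. A common divisor that left the length whole went unseen, so the read total of a tumor is a close lower estimate. On simulated counts the recovery returned exactly the simulated reads for 99.28% of genes above 0 in all 6 libraries. The recovered totals were 16868679, 14802701 and 13531587 reads for vehicle tumors 1, 2 and 3 and 14708337, 14045172 and 13691168 for DATS tumors 1, 2 and 3. The relative values of 1 read were proportional to median-of-ratios size factors of the recovered reads and not to the read totals, so that the deposited FPKM had been scaled between tumors by such factors. The FPKM totals differed: 608193, 656017 and 566304 in the vehicle tumors and 710096, 696676 and 662528 in the DATS tumors.

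The main tests were chosen for FPKM before the data were examined, as were the gene lists, the rule for naming genes and the alternatives. Exceptions were 2 alternatives and several further tests, named below. Genes with a mean of 1 FPKM or more over the 6 tumors were kept (13631 genes), and log2(FPKM + 1) was analysed with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, group as the only term, two-sided). Log2 differences are DATS minus vehicle on the log2(FPKM + 1) scale, which understates the change of genes of low value. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Gene lists with at least 5 kept members were tested with limma's camera, which compares a list with the other genes, at a preset correlation between genes of 0.01, with adjustment over the lists. At that preset the genes of a list are treated as nearly independent. These p-values therefore rest mainly on the spread between genes and do not measure the spread of a list between tumors. Each list was also tested with the correlation estimated from the data and with fry, which tests whether the genes of a list move on balance in 1 direction. The 35 lists held 839 symbols of pathways linked to garlic sulfur compounds or to mammary tumors, of cell types that a mammary tumor could hold and of sample quality. A symbol held by more than 1 list was counted in each. Matching gave 799 rows directly and 11 through older names in the RefSeq gene table of assembly GRCr8. A symbol on more than 1 row of the deposited table was counted for each row. The lists of sample quality were immediate early genes, ribosomal proteins and mitochondrially encoded genes. The share of the total variance lying between the groups was tested by an exact permutation over the 10 splits of 3 tumors against 3, whose smallest possible p is 0.1. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

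Genes were named by rule. With fewer than 20 genes called, the rule took the 10 highest and the 10 lowest log2 differences among kept genes with an unadjusted limma p under 0.05 and no overlap between the groups. It also took the 4 members with the smallest p of each called list and of 7 lists tied to what DATS is known for, and Foxq1, Lep, Nqo1, Hmox1, Mki67, Esr1 and Pgr whatever their values. Rows whose symbol begins with LOC, RGD or AABR and predicted pseudogenes were passed over in the first part, 6 among the highest and 2 among the lowest. The fit was tested on simulated data with the means and spreads of the 13631 genes, in which 100 genes were changed by 1 and 100 by 2 on the log2 scale. It called 20% of the former, 62% of the latter and 4 unchanged genes, and 0 genes when nothing was changed. When each changed gene was given the median spread, it called 10% and 76%.

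The alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, a minimum mean of 5 FPKM, median-of-ratios scaling over the kept genes, quantile normalization, rescaling to equal totals (TPM), limma without trend, with sample weights and with robust variances, the replicate number as a block, and leaving out each tumor in turn. For the lists under robust variances, camera was run on the moderated statistics. The 2 alternatives chosen after seeing the data were limma-voom on the recovered reads and removal of the trend of each tumor's values on gene length by local regression with a span of 0.5.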

Results

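Expression was measured in 6 MNU-induced mammary tumors, 3 of rats given corn oil and 3 of rats given DATS in corn oil, to find which transcripts differ in tumors of DATS-treated animals. The recovered depth was 13531587 to 16868679 reads per tumor, and between 17684 and 18330 genes were above 0 in each.

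No single gene was called between DATS and vehicle tumors. Of 35 gene lists 10 were called by camera at the preset correlation, and 0 with an estimated correlation (lowest adjusted p = 0.882) or with fry (0.901). The correlation estimated within the lists had a median of 0.32 and lay above the preset 0.01 in 34 of them. Ribosomal protein genes, nuclear genes of oxidative phosphorylation, luminal and myoepithelial markers, immediate early genes and genes of hydrogen sulfide and cysteine metabolism were called higher in DATS tumors at the preset correlation. Skeletal muscle genes, matrix and fibroblast genes, genes of epithelial-mesenchymal transition and genes of glycolysis and hypoxia were called lower. The called lists moved by a median of 0.14 to 0.43 on the log2 scale in either direction, apart from the skeletal muscle list at -1.56. Among 13631 genes, limma called 0, with a lowest adjusted p of 0.819. On simulated data the same fit called 20% of genes changed by 1 and 62% of those changed by 2 on the log2 scale. With the median spread for each changed gene it called 10% and 76%. A count of 0 therefore does not show that no gene changed. At an unadjusted p under 0.05 there were 797 genes, or 5.85%, of which 510 were higher and 287 lower in DATS tumors, and limma-voom on the recovered reads also called 0, with 704 genes at an unadjusted p under 0.05. The groups did not overlap for 1666 genes, 12.22% of those tested, where chance gives 10%. The median half-width of the 95% confidence interval of a log2 difference was 0.57. With the values rescaled to equal totals, which moved the median of all genes by -0.17, the genes at an unadjusted p under 0.05 were 129 higher and 905 lower. The medians of the 10 called lists kept their sign under each scaling but not their size. With equal totals those of the 6 lists called higher were 0.08 to 0.25, and those of the 4 lists called lower were -1.86 to -0.32, of which 3 were no longer called.

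Over the whole profile the tumors did not separate by treatment. The share of variance between the groups was 18.8%, where 20% is the average with no effect, and 7 of the 10 splits gave as large a share (exact permutation p = 0.7). The median correlation of log2 values was 0.924 between tumors of the same group and 0.933 between tumors of different groups. No member of any list was called, either over all genes tested or adjusted over the list alone.

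**Figure D1:**
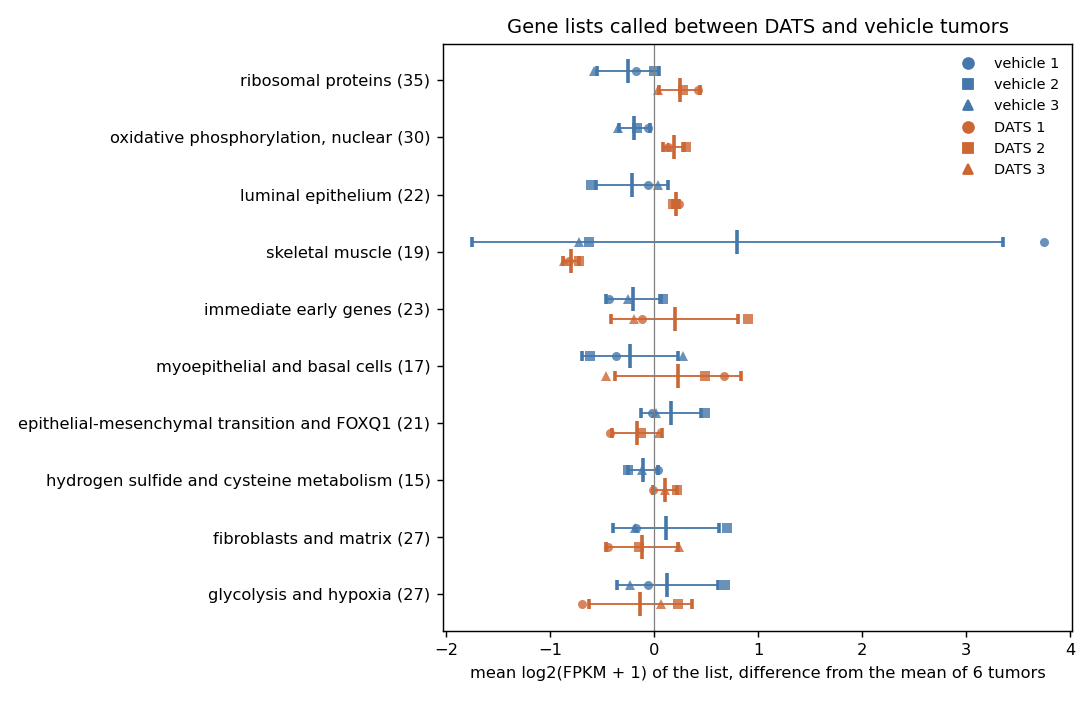
Mean log2(FPKM + 1) of each called gene list in each tumor, as the difference from the mean of the 6 tumors, with the number of members in parentheses; symbols are single tumors, vertical marks group means and bars 1 SD (n = 3). The 3 DATS tumors lie above the 3 vehicle tumors for ribosomal proteins, oxidative phosphorylation and luminal epithelium, and the skeletal muscle difference comes from vehicle tumor 1 at 3.75. Of the 35 lists tested, 3 had means that did not overlap between the groups, where chance gives 10%.

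Ribosomal protein genes were higher in DATS tumors for 33 of 35 members, with a median log2 difference of 0.43 (camera adjusted p = 3.66e-11; adjusted p = 0.882 with an estimated correlation). Rpl13, a protein of the large ribosomal subunit, had 2430 ± 363 FPKM in DATS and 1274 ± 245 in vehicle tumors (SD, n = 3), a log2 difference of 0.94 ± 0.24 (SE). Rps14, of the small subunit, had 2635 ± 709 against 1381 ± 188 FPKM. Rpl30 and Rpl11 had log2 differences of 0.56 and 0.69. The nuclear genes of oxidative phosphorylation were higher for 27 of 30 members, with a median of 0.26 (camera adjusted p = 1.43e-06; adjusted p = 0.882 with an estimated correlation). Ndufv1, the flavin-binding subunit of complex I, had 107 ± 8.85 against 75.4 ± 4.19 FPKM (SD, n = 3), and the DATS tumors lay above the vehicle tumors. Ndufb10 of complex I and Cox5b of cytochrome c oxidase had log2 differences of 0.68 ± 0.23 and 0.92 ± 0.31 (SE), and Ndufa1, also of complex I, one of 4.03 ± 1.42, with DATS tumors at 75.9, 166 and 2.03 FPKM and vehicle tumors at up to 1.60. Both lists were called without each tumor in turn, with medians of 0.33 to 0.57 for ribosomal proteins and 0.20 to 0.32 for oxidative phosphorylation. Scaling reduced them: quantile normalization gave medians of 0.12 (camera adjusted p = 0.0224) and 0.09 (0.0484), and equal totals gave 0.25 and 0.08. For the list means the 3 DATS tumors lay above the 3 vehicle tumors in both lists (exact permutation p = 0.1 each, the smallest possible). Of the 35 lists tested, 3 reached that p, where chance gives 10%, so this separation does not set the 2 lists apart. The oxidative phosphorylation means include Ndufa1, whose reads shared with near-identical copies were not examined.

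Gene length moved with the groups beside these lists. Genes of 500 to 1000 bp had a median log2 difference of 0.14, genes over 6000 bp one of -0.09, and genes under 200 bp one of -0.12. Over genes of 200 bp or more, the slope of a tumor's values per doubling of length was 0.08 in vehicle tumor 3, -0.04 in DATS tumor 2 and -0.06 in DATS tumor 3, and within 0.02 of 0 in the other tumors. Its difference between the groups was -0.06 (exact permutation p = 0.3). The median implied length was 718 bp in the ribosomal list and 1022 bp in the oxidative phosphorylation list. With the length trend removed, an alternative added after seeing the data, both lists were still called, with medians of 0.29 and 0.13.

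**Figure D2:**
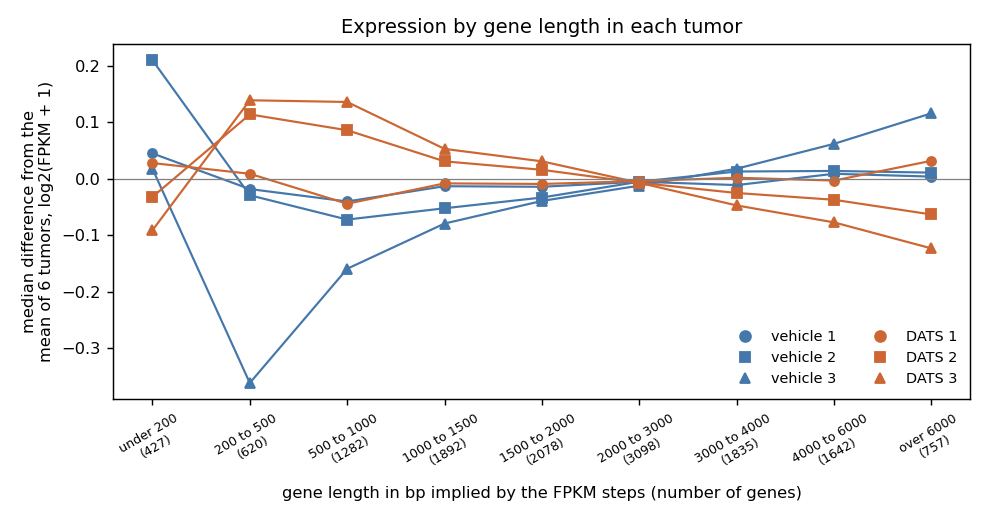
Median difference of each tumor from the mean of the 6 tumors on the log2(FPKM + 1) scale, for genes in bins of implied length in bp, with the number of genes in each bin; lines are single tumors. Genes of 200 to 500 bp were lowest in vehicle tumor 3 (-0.36), and DATS tumors 2 and 3 were above the other tumors between 200 and 2000 bp.

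Luminal epithelial markers were higher in DATS tumors for 21 of 22 members, with a median log2 difference of 0.38 (camera adjusted p = 0.000134; adjusted p = 0.882 with an estimated correlation). The tight junction claudins led the list. Cldn4 had 214 ± 40.2 FPKM in DATS and 120 ± 21.2 in vehicle tumors (SD, n = 3), Cldn3 255 ± 35.7 against 144 ± 70.8, and Cldn7 230 ± 81.3 against 136 ± 30.4. Ovol1, an epithelial transcription factor, had a log2 difference of 0.53. Myoepithelial and basal markers were higher for 15 of 17 members (median 0.31, camera adjusted p = 0.0208; adjusted p = 0.882 with an estimated correlation). Myl9, a regulatory myosin light chain, had 406 ± 163 against 207 ± 42.8 FPKM (SD, n = 3), and Actg2, Krt14 and Acta2 had log2 differences of 1.12, 0.68 and 0.83. Vehicle tumor 2 had the lowest mean of both lists, 0.61 below the average tumor in each, on the log2 scale. Without it the luminal median was 0.23 (adjusted p = 0.119) and the myoepithelial one 0.09 (0.504), and the latter call was also lost without DATS tumor 1 (median 0.20, adjusted p = 0.649) and without DATS tumor 2 (0.27, 0.0764). It rose to 0.58 (0.000124) without vehicle tumor 3 and to 0.75 (5.64e-07) without DATS tumor 3, where the luminal median was 0.23 (0.00143).

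Genes of epithelial-mesenchymal transition were lower in DATS tumors for 17 of 21 members, with a median of -0.34 (camera adjusted p = 0.0208; adjusted p = 0.882 with an estimated correlation). Tgfbi, a matrix protein induced by TGF-beta, had 30.1 ± 4.24 FPKM in DATS and 43.8 ± 10.1 in vehicle tumors (SD, n = 3). The proteases Mmp3 and Plau and the transcription factor Zeb1 had log2 differences of -1.53 ± 1.03, -0.50 ± 0.38 and -0.31 ± 0.25 (SE). Fibroblast and matrix genes were lower for 23 of 27 members (median -0.14, camera adjusted p = 0.0391; adjusted p = 0.882 with an estimated correlation). The fibrillar collagen chain Col5a2 had 65.2 ± 1.52 against 92.5 ± 12.0 FPKM (SD, n = 3), and Col6a1, Lum and Fbn1 had log2 differences of -0.67, -0.31 and -0.56. Vehicle tumor 2 was the highest tumor of both lists, by 0.49 and 0.70 above the average tumor. Markers of T and NK cells (1.17), granulocytes and mast cells (0.85), MHC class II and dendritic cells (0.74), B and plasma cells (0.695) and macrophages (0.69) were also highest in it. Without it the median was -0.16 for the transition list (adjusted p = 0.168) and -0.01 for the matrix list (0.896), and without DATS tumor 1 they were -0.14 (0.353) and -0.01 (0.783). The matrix list was also not called without DATS tumor 2 (median -0.18, adjusted p = 0.0764). In the other direction, its median was -0.36 (0.00265) without vehicle tumor 3 and -0.34 (0.000108) without DATS tumor 3, and that of the transition list was -0.525 (0.00695) without vehicle tumor 1.

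Skeletal muscle genes were lower in DATS tumors for 18 of 19 members (median -1.56, camera adjusted p = 0.000134; adjusted p = 0.882 with an estimated correlation). The values came from vehicle tumor 1, in which 18 of the 19 members were highest. Acta1, skeletal muscle actin, was at 677 FPKM there and at 2.26 or less in each of the other tumors, and Ckm, muscle creatine kinase, was at 131 FPKM against 0.576 or less. Cox6a2 and Neb, a muscle subunit of cytochrome c oxidase and a thin filament protein, were at 47.2 and 4.95 FPKM in that tumor. Without vehicle tumor 1 the list median was -0.14 and the adjusted p was 0.305, and without vehicle tumor 3 they were -2.46 and 4.82e-08.

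Immediate early genes were higher for 21 of 23 members (median 0.37, camera adjusted p = 0.0054; adjusted p = 0.882 with an estimated correlation), and DATS tumor 2 was 0.90 above the average tumor. The list had been fixed for sample quality, and its means overlapped between the groups (exact permutation p = 0.4). Whether it reflects treatment or sample quality was not tested. Junb had 224 ± 38.2 FPKM in DATS and 157 ± 19.0 in vehicle tumors (SD, n = 3). Egr1, Jund and Fos, also transcription factors of this list, reached 124, 378 and 103 FPKM in DATS tumor 2. The list was not called without DATS tumor 2 (median 0.12, adjusted p = 0.49) or without vehicle tumor 1 (0.375, 0.112), and its median rose to 0.59 (3.56e-05) without DATS tumor 3. Genes of glycolysis and hypoxia were lower for 22 of 27 members (median -0.18, camera adjusted p = 0.0496; adjusted p = 0.882 with an estimated correlation). Pkm, a pyruvate kinase, had another kept row in this list, which counts as a further member. On the row with the smaller p it had 353 ± 75.1 against 527 ± 118 FPKM (SD, n = 3). Egln3, Hk2 and Ero1l had log2 differences of -0.96, -0.66 and -0.71. The median turned to 0.03 without vehicle tumor 2 and to 0.13 without DATS tumor 1 (adjusted p = 0.903 and 0.824), and it was 0.03 with sample weights. It was -0.37 (0.000262) without vehicle tumor 3, -0.32 (0.000409) without DATS tumor 2 and -0.35 (0.00594) without DATS tumor 3.

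The hydrogen sulfide and cysteine metabolism list, fixed because DATS releases hydrogen sulfide, was higher for 11 of 15 members, with a median of 0.29 (camera adjusted p = 0.0261; adjusted p = 0.882 with an estimated correlation). Mpst, which makes sulfide from 3-mercaptopyruvate, had 84.6 ± 8.98 FPKM in DATS and 60.4 ± 8.55 in vehicle tumors (SD, n = 3), and Suox, sulfite oxidase, had 17.7 FPKM against 12.3 ± 2.58, with the 3 DATS tumors above the 3 vehicle tumors. Cbs and Tst had log2 differences of 0.55 ± 0.30 and 0.36 ± 0.20 (SE). The call was lost without vehicle tumor 2 (median 0.21, adjusted p = 0.119), without DATS tumor 2 (0.30, 0.0764), with quantile normalization (0.185, 0.0571) and with the length trend removed (0.25, 0.0575).

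Other lists fixed for known actions of DATS, those of NRF2, apoptosis, G2/M, JAK-STAT3 and estrogen response, were not called with all 6 tumors on the values as deposited, unlike the transition list above. NRF2 antioxidant targets had 17 of 28 members lower and a median of -0.11 (camera adjusted p = 0.248), and they were called lower with quantile normalization (-0.17, 0.0484) and without vehicle tumor 1 (-0.25, 0.049). Txnrd1, Gsta1, Gclc and Akr1b8 had log2 differences of -0.33, -1.02, -0.36 and -1.02, and Nqo1 and Hmox1 had -0.22 ± 0.39 and -0.68 ± 0.73 (SE). Hmox1 ranged from 16.8 to 109 FPKM over the 6 tumors. Apoptosis regulators had 15 of 27 members lower (adjusted p = 0.772). Within them Bik, which encodes a BH3-only death promoter, had 15.6 ± 5.30 FPKM in DATS and 5.00 ± 1.93 in vehicle tumors (SD, n = 3; log2 difference 1.47 ± 0.33, SE), and Pmaip1, Casp8 and Fas had -0.48, -0.38 and -0.58. G2/M genes had a median of -0.07 (camera adjusted p = 0.571), with Hmmr, Ttk, Kif23 and Birc5 at log2 differences of -0.52, -0.46, -0.23 and 0.33 and Mki67 at -0.28 ± 0.44 (SE). Without vehicle tumor 1 their median was 0.24 and the list was called higher (camera adjusted p = 0.023), whereas without vehicle tumor 3 and without DATS tumor 3 it was called lower, with medians of -0.445 (1.47e-07) and -0.28 (0.00691).

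The JAK-STAT3 and leptin list had a median of -0.07 (camera adjusted p = 0.772), with Junb as above, Cish at a log2 difference of 0.55 and the cytokine receptors Osmr and Il6st at -0.45 and -0.43. Lep lay below the filter, at 0.109 FPKM or less in every tumor, and Foxq1 was not analysed here. The estrogen and progesterone response list had a median of 0.15 (camera adjusted p = 0.617), which turned to -0.013 with equal totals, and held members of both directions. Myb, a transcription factor of estrogen receptor-positive tumors, had 7.97 ± 2.16 FPKM in DATS and 15.2 ± 2.22 in vehicle tumors (SD, n = 3). Esr1, estrogen receptor alpha, had 4.08 ± 0.758 against 7.55 ± 3.07 FPKM, with overlapping groups, and Pgr, the progesterone receptor, had 7.94 ± 5.52 against 6.98 ± 4.51. Rara and Fgfr2 had log2 differences of 0.45 and 0.58. The differences of Nqo1, Mki67, Kif23, Birc5 and Pgr changed sign when 1 tumor was left out.

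Among genes that were not called, 699 had an unadjusted limma p under 0.05 with no overlap between the groups, 438 higher and 261 lower in DATS tumors. The 10 highest were Ndufa1, Rpl7a, Timm17b, AC131806.3, Fam25a, Dusp11, Rps28, AC142126.2, SCARNA17 and Ckmt1b, with log2 differences of 1.63 to 4.03. Several varied widely within the DATS group. Ndufa1 was near the vehicle tumors in DATS tumor 3, at 6 recovered reads there and 6 in vehicle tumor 1. Fam25a had 2 reads in both DATS tumor 1 and vehicle tumor 1, and AC142126.2 had 12 in both DATS tumor 1 and vehicle tumor 3. For these genes only the scaling between tumors kept the groups apart. SCARNA17 rested on 1 to 15 reads per tumor and AC131806.3 on 0 to 83. Rpl7a was at 922, 62.2 and 281 FPKM in DATS tumors 1, 2 and 3 and at 22.9 to 39.3 in vehicle tumors, and Timm17b, of the inner mitochondrial membrane translocase, at 5.65, 28.4 and 29.5 against 0.532 to 4.26. Rps28 had 1124 ± 536 against 311 ± 149 FPKM (SD, n = 3). Rpl7a, Rps28 and Hmgb3 each had another row of the same symbol in the table, and reads shared with near-identical copies were not examined for these genes, Ndufa1 or Tma7.

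The 10 lowest were Tma7, Mcpt8, SNORA15, Mir3593, Hmgb3, AC095267.2, SNORA44, snoU2-30, SNORD73 and U6, with log2 differences of -2.40 to -1.63. Of these, 6 were small noncoding RNAs of at most 18 recovered reads in any tumor, and SNORA44 and U6 were listed at 0 in the 3 DATS tumors. Hmgb3, a high mobility group chromatin protein, had 1.16 ± 0.141 FPKM in DATS and 6.39 ± 1.82 in vehicle tumors (SD, n = 3), a log2 difference of -1.75 ± 0.23 (SE), and rested on 22 to 241 reads per tumor. Mcpt8, a mast cell and basophil protease, had 2.03 ± 1.14 against 15.1 ± 10.8 FPKM, and Tma7 had 6.18 ± 0.798 against 43.4 ± 26.9. Their limma adjusted p was 0.819 or more, as for every gene tested.

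**Figure D3:**
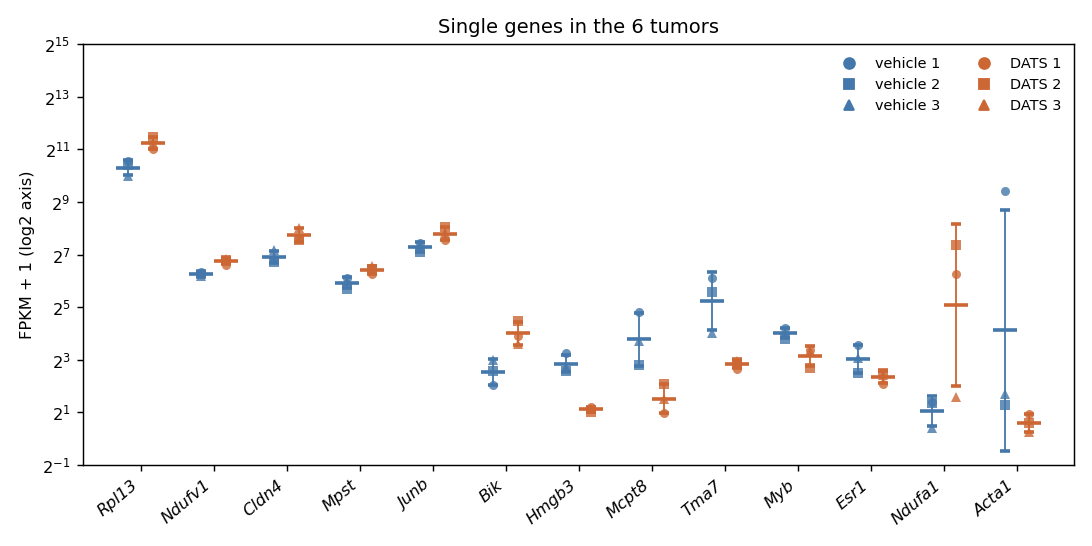
FPKM + 1 on a log2 axis for 13 of the named genes in each tumor; symbols are single tumors, horizontal marks the mean and bars 1 SD of the log2 values (n = 3 per group). The groups do not overlap for Rpl13, Ndufv1, Cldn4, Mpst, Junb, Bik, Hmgb3, Mcpt8, Tma7, Myb, Ndufa1 and Acta1, and they overlap for Esr1. Ndufa1 in DATS tumors and Acta1 in vehicle tumors spread most widely. The 13 genes were picked for display without a fixed rule. Hmgb3, Mcpt8, Tma7 and Ndufa1 had been named for their lack of overlap, which was thus fixed in advance. Nqo1, Hmox1, Mki67 and Pgr, whose groups overlap, are not shown, and 12.22% of all genes tested did not overlap.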

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

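The alternatives with limma-voom on recovered reads and with the length trend removed were chosen after seeing the data. The number of genes called was 0 under each alternative, with lowest adjusted p values between 0.138 and 0.999. The share of variance between the groups was 18.1% to 20.4% under the other pseudocounts, filters and scalings, and 19.8% to 28.2% with 1 tumor left out, where fewer samples raise the average share. The number of lists called was 0 with an estimated correlation and 0 with fry. It was 7 to 10 under the other settings with all 6 tumors apart from the block, and 6 to 17 with 1 tumor left out, with 17 without vehicle tumor 1, 6 without vehicle tumor 2 and 17 without DATS tumor 3, and the cause was not tested. Apart from the estimated correlation and fry, settings with all 6 tumors ended calls of the matrix, glycolysis, transition, myoepithelial and sulfide lists, at adjusted p values of 0.0503 to 0.958, and of no other list. Quantile normalization gained a call of NRF2 targets (0.0484), no filter one of milk proteins (0.0179), and equal totals calls of milk proteins, interferon response and adipocytes (0.00449, 0.0225 and 0.0214), and 15 lists that were not called with all 6 tumors on the values as deposited were called with at least 1 of the tumors left out. With the replicate number as a block, 0 genes and 14 lists were called. The labels do not say whether the numbers pair the tumors. The deviations of same-numbered tumors from their group means correlated at 0.15, -0.02 and -0.12 across genes. These values gave no sign of pairing but cannot exclude it with so few tumors.

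Over 82 named genes and all alternatives, 1540 log2 differences were computed, of which 1531 kept their direction. Of the 9 that reversed, 8 were with 1 tumor left out. Leaving out a tumor gave log2 differences of -0.460 to 0.033 for Kif23, -0.165 to 0.671 for Birc5, -0.502 to 0.125 for Nqo1, -0.761 to 0.074 for Mki67 and -0.326 to 0.575 for Pgr, and rescaling to equal totals gave -0.012 for Pgr. The median of the glycolysis and hypoxia list turned to 0.033 with sample weights and was -0.37 to 0.13 with 1 tumor left out. Leaving out vehicle tumor 1 turned the median of the G2/M list to 0.24, in a range of -0.445 to 0.245, and leaving out vehicle tumor 2 turned that of the T and NK cell list to 0.54, in a range of -0.397 to 0.540; the cause was not tested. Genes of few reads, the small RNAs above all, limit what depth allows: 1 read was a whole step of their value.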

Other observations

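The tests of a low vehicle tumor, of muscle tissue in a vehicle tumor, of an extreme vehicle tumor, of the splits of the gene count and of lists on values simulated without correlation were chosen after the results were seen, as was the removal of the length trend.

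Several other gene groups varied widely from tumor to tumor and were not called with all 6 tumors on the values as deposited. Each was called under other settings, but at the preset correlation. With an estimated correlation no list was called with all 6 tumors (lowest adjusted p = 0.882). The correlation estimated within the lists was 0.32 at the median, so the calls below do not decide whether treatment made a difference, which stays open. Milk protein and secretory genes, which mark lactational differentiation, were 2.70 above the average tumor on the log2 scale in DATS tumor 1 and 2.14 below it in DATS tumor 3, and vehicle tumors ranged from -1.50 to 1.12 (median log2 difference 1.13, camera adjusted p = 0.133). They were called higher with no filter (adjusted p = 0.0179), with equal totals (0.00449), with the block (0.00704), without vehicle tumor 1 (median 1.97, adjusted p = 0.0195) and without DATS tumor 3 (2.55, 5.64e-07). T and NK cell genes were 1.17 above the average in vehicle tumor 2, macrophage genes 0.69 and MHC class II and dendritic cell genes 0.74 (adjusted p = 0.772, 0.169 and 0.269). T and NK cell genes were called higher without that tumor (median 0.54, adjusted p = 8.4e-05), macrophage genes lower without vehicle tumor 1 (-0.66, 1.13e-06), and MHC class II and dendritic cell genes lower without vehicle tumor 1 (-0.45, 0.00771) and without DATS tumor 3 (-0.32, 0.0304). G2/M and S phase genes were highest in vehicle tumor 1, by 0.70 and 0.73, and lowest in vehicle tumor 3, by -0.78 and -0.53. S phase genes were lower in DATS tumors for 23 of 27 members (camera adjusted p = 0.0724), and were called lower without vehicle tumor 3 (median -0.535, adjusted p = 8.58e-08) and without DATS tumor 3 (-0.42, 0.000246). Adipocyte genes were 0.84 above the average in DATS tumor 1, and genes of NF-kappaB and inflammatory cytokines 0.86 above it in vehicle tumor 3 (adjusted p = 0.157 and 0.0795). The former were called higher without DATS tumor 2 (median 0.70, adjusted p = 4.25e-05), with equal totals (0.0214) and with the block (0.0369), and the latter lower without vehicle tumor 1 (-0.71, 0.000186), without DATS tumor 2 (-0.44, 0.0209) and with the block (0.0181).

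The remaining lists were not called on those values either. Medians above 0 in DATS tumors were found for interferon response (0.18, camera adjusted p = 0.0775), Schwann and nerve (0.28, 0.259), keratinocytes and skin (0.29, 0.366), erythroid cells (0.43, 0.373), fatty acid and cholesterol synthesis (0.05, 0.436), mammary stem and progenitor markers (0.22, 0.775) and mitochondrially encoded genes (0.05, 0.919). They were below 0 for granulocytes and mast cells (-0.26, 0.149), endothelium and pericytes (-0.22, 0.223), B and plasma cells (-0.20, 0.373), p53 targets (-0.08, 0.556) and heat shock response (-0.04, 0.617). Some were called in the same direction when 1 tumor was left out: interferon response without vehicle tumor 2 (median 0.29, adjusted p = 0.00693), DATS tumor 2 (0.27, 0.021) or DATS tumor 3 (0.28, 0.0203), fatty acid and cholesterol synthesis without vehicle tumor 1 (0.21, 0.0375) or DATS tumor 1 (0.25, 0.0182), and erythroid cells without vehicle tumor 3 (0.86, 0.0291) or DATS tumor 2 (0.91, 0.0407). So were Schwann and nerve without DATS tumor 3 (0.38, 0.0124), endothelium and pericytes without vehicle tumor 1 (-0.57, 0.000128) or DATS tumor 3 (-0.405, 0.021), and granulocytes and mast cells without vehicle tumor 1 (-0.75, 0.000408). Interferon response was also called with equal totals (0.0225), and granulocytes and mast cells with the block (0.0332). With equal totals or quantile normalization the medians of the ATF4, mitochondrially encoded and, with equal totals alone, fatty acid lists were below 0. The ATF4 and unfolded protein response list had a median of 0.03 while camera ranked it lower (adjusted p = 0.661). The median and the mean differed in sign for heat shock response, apoptosis regulators and mitochondrially encoded genes, with means of 0.002, 0.01 and -0.13.

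Ribosomal protein and oxidative phosphorylation genes were called higher in DATS tumors as lists at the preset correlation, as are the adjusted p values below, and neither was called with an estimated one (0.882) or with fry (0.901). Also higher were genes of 200 to 2000 bp by their medians, while the 427 genes under 200 bp had a median of -0.12. If the length trend were the whole cause, its removal would bring the ribosomal median near 0. It left 0.29 of 0.43 (camera adjusted p = 6.19e-08), and the oxidative phosphorylation median at 0.13 of 0.26 (0.00162). This argues against the implied gene length as the whole cause and leaves it open for part of both. The lengths of the transcripts present in the tumors can differ from the implied ones and were not examined. Scaling between tumors stays open for part of both too, since quantile normalization left 0.12 and 0.09 (0.0224 and 0.0484). Vehicle tumor 3 was the lowest tumor of both lists and was picked after the results were seen. Without it the medians were 0.33 of 0.43 and 0.23 of 0.26 (camera adjusted p = 2.96e-07 and 0.00118). That tumor alone did not make these medians. The p-values add little, since the preset correlation lies below the one estimated within most lists. A treatment effect and a difference in RNA quality or tumor makeup remain open, and the list means differed by 0.50 ± 0.21 and 0.38 ± 0.10 (SE between tumors). The mean of 0.38 includes Ndufa1 with a log2 difference of 4.03 and lies above the list median of 0.26.

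Skeletal muscle genes were called lower in DATS tumors at the preset correlation (adjusted p = 0.882 with an estimated one), with vehicle tumor 1 apart from the others. A candidate explanation is muscle tissue in that sample. Of 19 members 18 were highest there, with a median log2 difference of 4.70 from the other 5 tumors, and without it the list median was -0.14 in place of -1.56. Acta1 at 677 FPKM and Ckm at 131 FPKM were abundant in that tumor alone. A tumor with muscle differentiation and a smaller difference by treatment remain open, untested.

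Matrix and transition genes were lower and luminal genes higher in DATS tumors at the preset correlation (adjusted p = 0.882 for each with an estimated one), and vehicle tumor 2 was the extreme tumor of each of these lists. It was picked for that, so the end of the 3 calls without it, with 1 tumor fewer, decides nothing. A candidate explanation is that this extreme vehicle tumor alone made the differences, and without it 1 of the 3 medians came close to 0, that of fibroblasts and matrix (-0.01 in place of -0.14). Luminal epithelium kept 0.23 of 0.38 and the transition list -0.16 of -0.34. The transition and matrix calls also ended without DATS tumor 1. The makeup of that tumor and a difference by treatment both remain open.

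The 10 splits of the 6 tumors are too few for a share under 0.05. For genes the real split called 0 and the highest of the other splits 1, and a comparison with 0 shows nothing. At an unadjusted limma p under 0.05 the real split gave 797 genes and the other splits 283 to 1139. Those above the real split gave 1000, 1085 and 1139, so this number does not set the treatment groups apart either. For lists the real split called 10, the fewest of all, and the other splits 11 to 22. The highest had vehicle tumor 1 and DATS tumors 1 and 3 on the same side. All 10 splits called at least as many lists as the real one, so the number of list calls does not set the treatment groups apart. In 20 simulations with no correlation between genes the same test called 0 or 1 list, and the correlation estimated within the real lists was 0.32 at the median, so that genes of a list varied together between tumors beyond what the preset 0.01 allows for. Whether a structure of the tumors lies behind this was not tested.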
